A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

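Small RNA bound to Argonaute (Ago1) was sequenced from Schizosaccharomyces pombe, the fission yeast, in 6 libraries. The labels named a wild-type h+ strain, no tagged Ago1 allele, and 2 groups of 3 replicates: growing cells at 0 h, and cells 24 h after nitrogen was removed. Per the labels' protocols, cells were grown in the minimal medium EMM at 32 °C and washed into EMM without nitrogen. Frozen cells were ground, Ago1 complexes were pulled down on magnetic beads that bind the FLAG peptide, and RNA of 20 to 30 nucleotides was cut from a gel before library preparation.

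Each deposited file held raw read counts made by the authors, whole numbers for 6878 feature IDs plus 5 HTSeq tally lines. Cutadapt, Bowtie2 2.1.0 and HTSeq 0.6.1, with the genome build ASM294v2, were named per the submitters' processing notes. Their options, including strand handling and the treatment of reads with several equal placements, were not given in the sources used here. Of 576 features lying wholly inside a feature on the opposite strand, 492 (85.4%) had a count in at least 1 library. HTSeq gives such a feature no count when strand is ignored, so the counting had used strand. Which strand was taken as a feature's own was not given in the sources used here. Reads on the strand opposite a feature, with no feature of their own, would be tallied as in no feature.

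The tally lines were kept out of library totals and tests. They showed that 90.3 to 96.4% of the aligned reads per library had been set aside for low mapping quality, which includes reads with several equal placements. Counts therefore covered only sequence that could be placed confidently, and copies of repeats, ribosomal RNA and near-identical genes were under-counted to an unknown degree. No feature was typed as ribosomal RNA, and the 13 Tf2 retrotransposon features had 0 counts in every library. Reads not aligned were listed as 0, so the depth before alignment was unknown.

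IDs were looked up in an NCBI RefSeq annotation of assembly ASM294v3, used for names, feature types, descriptions, neighbours and membership of chromosomal regions. Of the 6878 IDs, 6706 matched directly, 8 matched through an older ID, and 164 did not match, among them 36 with the prefix SPMIT that marks the mitochondrial genome. Because the build of the files was older, no coordinates are given. Regional lists rest on windows set for ASM294v2 but applied to positions of ASM294v3, so membership at window edges may differ.

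Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, a robust quasi-likelihood fit on group alone and a two-sided test, with Benjamini-Hochberg adjustment over 1716 tested features and a threshold of 0.05. Standard errors (SE) were the log2 fold change divided by the square root of the F statistic. CPM values were scaled by the TMM factors. Where a group had no count, a fold was a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the pooled ratio was given with a 95% counting interval. Gene lists with at least 3 tested members were tested with camera from limma 3.58.1, at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Shares of each feature class were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.10. Intervals on single-library shares were Wilson 95% intervals. Reads had no molecular identifiers, so intervals and floors covered counting error only.

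The lists, the main tests of features, lists and class shares, and the naming rule were fixed before the data were examined. The 5 pericentromeric noncoding RNAs, which are all tested noncoding RNAs of the pericentromeric list, were grouped after the data had been seen. The rule took the 8 largest rises and the 8 largest falls among features past the test, with no overlap between groups and a mean of at least 10 CPM, tRNA excluded. It added the 5 most abundant features of each group, then ago1, dcr1, clr4, tlh1 and tlh2, and up to 4 members with the smallest p in each list described.

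On simulated counts drawn from the means and totals of these libraries, with 200 features changed, the test recovered 0% of 169 tested features at a log2 change of 1. It recovered 86.4% of 162 at a log2 change of 2, with 7 unchanged features called, and 100% of 165 at 3, with 14 unchanged features called. The simulated groups shared 1 mean profile apart from the changed features, so the real shift in makeup was absent. In the real data some changes near 1 did pass, such as rpl1802 at -1.05 (edgeR adjusted p = 0.0354). With no change simulated, camera called 2 of 334 list tests over 20 simulations. Features were drawn independently, so that simulation could not show what correlation between genes does to the list tests. Correlations estimated from the data ran from -0.22 for the G1/S list to 0.82 for the SPMIT list. No pair of libraries agreed within sampling noise, since the smallest chi-square per degree of freedom was 5.72. The labels did not say that replicates were separate cultures, so p-values measured the spread between these samples, which may be technical.

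Alternatives covered other scalings, filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and other denominators for the class shares. Scaling by all aligned reads and thinning to the smallest assigned total were added after the data had been seen, as were some tests of explanations. Depth was tested in a linear model of the 6 libraries on group and log2 depth. Intervals on medians of list members came from 2000 bootstrap draws of the members, not of the libraries. No pull-down without a tag was analysed here. Permutation and Fisher tests used SciPy 1.17.1.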

Results

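Small RNA from pull-downs labelled as Ago1, the Argonaute protein of fission yeast RNA interference, was counted per annotated feature in growing cells (0h) and in cells held without nitrogen for 24 h (24h), with 3 libraries in each group. The 0h libraries held 48040, 112578 and 145861 reads assigned to features, out of 9697745, 22451181 and 24279396 aligned reads. The 24h libraries held 54393, 249986 and 758789 assigned reads, out of 1636419, 4636939 and 33555536. The labels named no tagged Ago1 allele, so that the RNA was Ago1-bound rests on the labels. The comparison asked which small RNAs were pulled down from growing cells and which after nitrogen starvation.

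The makeup of the assigned reads shifted from centromere repeats to protein-coding genes. These shares leave out reads in no feature, among them any from the opposite strand of a feature. Reads in no feature were most of the uniquely placed reads at 0h. They were 88.0% ± 4.63 of uniquely placed reads at 0h and 47.0% ± 4.92 at 24h (SD, n = 3, exact permutation p = 0.10). At 0h, 5 long noncoding RNAs of the pericentromeric repeats (SPNCRNA.231, SPNCRNA.232 and SPNCRNA.234 on chromosome I, SPNCRNA.359 and SPNCRNA.373 on chromosome II), which template the small RNAs that direct heterochromatin, held 41.6% ± 7.31 (SD, n = 3) of assigned reads. At 24h they held 2.67% ± 1.71 (SD, n = 3), 15.6-fold less. Protein-coding features held 44.7% ± 2.54 of assigned reads at 0h and 82.8% ± 2.08 at 24h (SD, n = 3 each). Every 24h library lay beyond every 0h library in these comparisons, and the two-sided exact permutation test gave p = 0.10 for each, the smallest value that 3 against 3 libraries allow.

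All long noncoding RNAs together were 45.2% ± 7.21 of assigned reads at 0h and 7.71% ± 1.03 at 24h, a difference of -37.53 percentage points. The 5 pericentromeric noncoding RNAs are part of this class and alone differed by -38.95 points, so the rest of the class did not fall in share. Per aligned read the whole class was 1.15-fold higher at 24h, and subtelomeric features were 1.39-fold higher. As shares of assigned reads, subtelomeric features were 0.379% ± 0.0350 and 0.0908% ± 0.0610. Features typed as snRNA or snoRNA were 0.150% ± 0.0224 and 0.595% ± 0.376 (all SD, n = 3, exact permutation p = 0.10). Shares of tRNA (6.11% ± 2.54 and 4.19% ± 1.23, exact permutation p = 0.20), of features with the SPMIT prefix (3.76% ± 2.90 and 4.70% ± 2.51, p = 0.70) and of the mating-type region (0.0988% ± 0.0122 and 0.120% ± 0.0215, p = 0.30) did not separate the groups. Per aligned read all 3 classes were higher in every 24h library, the mating-type region by 8.78-fold (exact permutation p = 0.10 each).

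**Figure D1:**
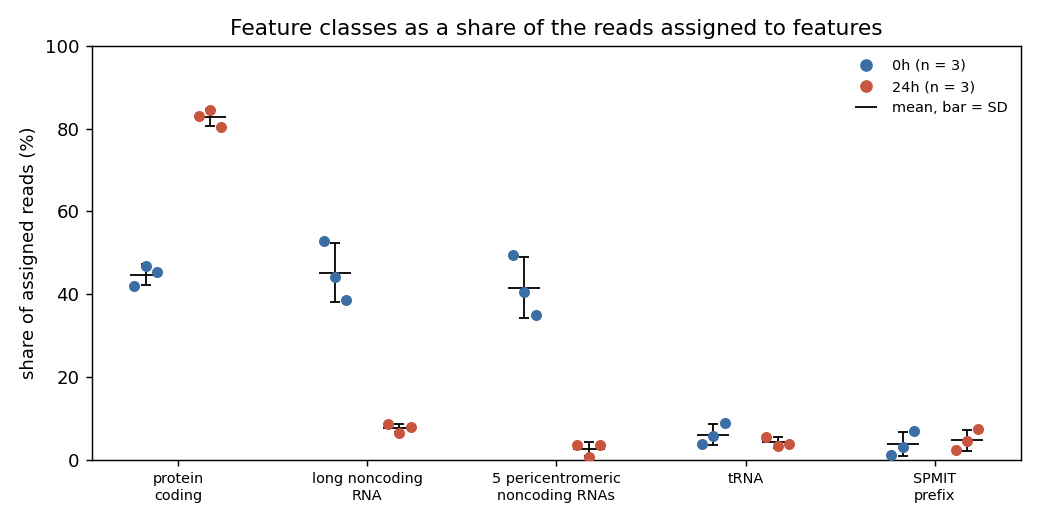
Share of assigned reads (%) in 5 feature classes, with 1 point per library, 0h in blue and 24h in red; the horizontal mark is the mean and the bar the SD over 3 libraries. The 5 pericentromeric noncoding RNAs, which are also part of the long noncoding class, averaged 41.6% at 0h and 2.67% at 24h, and protein-coding features 44.7% and 82.8%.

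Assigned reads were themselves a larger part of the aligned reads at 24h, 3.66% ± 1.59 against 0.533% ± 0.0592 at 0h (SD, n = 3, exact permutation p = 0.10). As CPM of all aligned reads, protein-coding features were 12.8-fold higher at 24h (30492 ± 13927 against 2383 ± 329), and the 5 pericentromeric noncoding RNAs were 2.73-fold lower (804 ± 417 against 2192 ± 222), again with no overlap between groups (SD, n = 3, exact permutation p = 0.10). On that scale tRNA features were 4.45-fold higher and SPMIT features 7.62-fold higher (exact permutation p = 0.10 each; 3.65 to 6.29 and 5.64 to 14.9 without each library in turn), while long noncoding RNAs as a class (1.15-fold, p = 0.60) and subtelomeric features (1.39-fold, p = 0.70) overlapped between groups and changed direction when a library was left out (from 0.976 to 1.34 and from 0.923 to 1.78). The fold ran from 9.62 to 15.4 for protein-coding features and from 2.15 to 3.64 for the fall of the 5 noncoding RNAs.

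**Figure D2:**
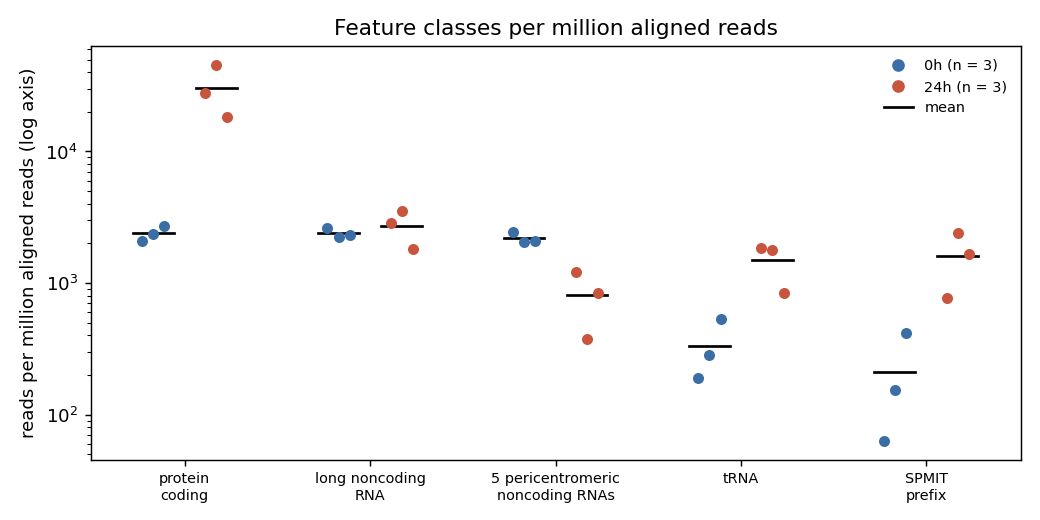
CPM of all aligned reads (log axis) for the same 5 feature classes, with 1 point per library, 0h in blue and 24h in red, and a line at the mean. Protein-coding, tRNA and SPMIT features lay higher in every 24h library, the 5 pericentromeric noncoding RNAs lower, at 804 against 2192, and long noncoding RNAs as a class overlapped.

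Of 1716 features with enough counts, 224 were higher and 220 lower at 24h, and 1272 did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). No overlap between the groups was seen for 755 of the tested features, where chance gives 10%. TMM scaling puts the typical feature at no change (median log2 fold change -0.02), so rises and falls are relative to it. With library totals alone the median was 0.69 and the calls were 568 higher and 95 lower. Per aligned read the median was 3.55, and the calls were 1611 higher and 4 lower, the 4 being SPNCRNA.232, SPNCRNA.1461, SPNCRNA.231 and the tRNA SPCTRNAGLY.12. Without 0h replicate 2 the higher calls numbered 110, and without 0h replicate 3 they numbered 139.

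The largest rises were in protein-coding genes that were almost without small RNA at 0h. Reads from prl65 (SPAC19A8.16) and hsp3105 (SPAC1F7.06, a glyoxylase of the ThiJ family) were absent at 0h and numbered 269 and 159 at 24h, at least 17-fold and at least 10.0-fold higher against a floor of 3 counts over the group. The cell wall gene psu2 had 1 count at 0h and 263 at 24h, a pooled ratio of 49.9 (95% counting interval 8.87 to 1977). The uncharacterised SPCPB16A4.06c had 3 and 1029 counts, a ratio of 65.0 (22.2 to 316), the enolase gene eno102 2 and 629, a ratio of 59.6 (16.4 to 493), and the transcription factor gene SPAC2H10.01 3 and 414, a ratio of 26.2 (8.89 to 127). The amino acid permease gene nrg1 rose by 5.08 (SE 0.63) and the formamidase-like gene SPAC869.04 by 4.96 (SE 0.81) on the log2 scale, from 4 counts each at 0h. Those of SPAC869.04 all lay in 0h replicate 2. Its change was 4.05 at the lowest without each library in turn. The highest value, 10.23, was fitted with no count left at 0h and does not measure a size. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 8 features had adjusted p between 0.00110 (nrg1) and 0.00864 (prl65). Each lay higher in every 24h library than in any 0h library. The naming rule required both a passing test and no overlap.

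The largest falls mixed centromeric transcripts with single euchromatic genes. SPNCRNA.232 went from 256962 ± 131895 to 5119 ± 3390 CPM (SD, n = 3), a log2 change of -5.65 (SE 1.12), and SPNCRNA.1461, a noncoding RNA beside fis1 on chromosome II, from 164 ± 55.9 to 1.61 ± 2.78 CPM, a change of -5.46 (SE 0.68). The thiamine-repressible acid phosphatase gene pho4 fell by 4.85 (SE 0.51), eng1, whose glucanase separates daughter cells, by 4.77 (SE 0.46), and SPAC644.09, a pyridoxal phosphate homeostasis gene, by 3.92 (SE 0.46) on the log2 scale. All 5 had adjusted p between 0.000494 and 0.00526 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They lay lower in every 24h library, which the naming rule also required. Scaled to aligned reads in edgeR, pho4 (-1.36, adjusted p = 0.104), eng1 (-1.37, adjusted p = 0.0792) and SPAC644.09 (-0.55, adjusted p = 0.466) no longer passed.

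At 0h the most abundant features were the pericentromeric SPNCRNA.232, SPNCRNA.359, SPNCRNA.231 and SPNCRNA.234, with the transporter gene SPBC530.02 on chromosome II ranking among them. SPBC530.02 and a pericentromeric noncoding RNA stayed among the 5 most abundant at 24h. SPBC530.02 was at 57609 ± 38770 CPM at 0h and 53391 ± 36344 CPM at 24h (SD, n = 3). Its log2 change of -0.11 (SE 0.88) was positive with library totals (0.56) and aligned reads (3.13). The highest feature at 24h was mfs2, a transporter gene of the major facilitator family, at 68612 ± 50444 CPM against 13149 ± 4576 at 0h, a log2 change of 2.38 (SE 0.87) that did not pass (adjusted p = 0.0665, edgeR's quasi-likelihood test, Benjamini-Hochberg), and passed without 24h replicate 2 (2.88, adjusted p = 0.00476). The signal recognition particle RNA srp7 (-0.33, SE 0.59) and SPMIT.01 (-0.10, SE 0.75) followed, with positive values with totals (0.40 and 0.53) and aligned reads (3.24 and 3.14).

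In the pericentromeric list, fixed by position, all 5 tested noncoding RNAs fell, with log2 changes of -4.73 (SPNCRNA.373, SE 0.80), -5.14 (SPNCRNA.231, SE 0.99), -5.65 (SPNCRNA.232, SE 1.12), -3.83 (SPNCRNA.359, SE 1.01) and -3.69 (SPNCRNA.234, SE 1.03). The 1 member that rose was per1, a protein-coding gene at the edge of the window. The list had camera adjusted p = 0.000920, and adjusted p = 0.289 with an estimated correlation. The count of falls was also 5 adjusted over the list alone and with library totals, but 2 per aligned read. It was 3 without 0h replicate 2. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg ran from 0.00301 to 0.0228. It was 0.0640 and 0.0655 for SPNCRNA.359 without 0h replicate 2 and 24h replicate 1, and 0.0660 and 0.0605 for SPNCRNA.234 without 0h replicate 1 and 0h replicate 2. Per aligned read in edgeR, SPNCRNA.232 (-2.43, adjusted p = 0.00277) and SPNCRNA.231 (-1.85, adjusted p = 0.0264) passed, whereas SPNCRNA.373 (-1.54, adjusted p = 0.0619), SPNCRNA.359 (-0.82, adjusted p = 0.291) and SPNCRNA.234 (-0.45, adjusted p = 0.579) did not.

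At the chromosome ends, the RecQ-type helicase genes tlh1 and tlh2 fell by 3.62 (SE 0.91) and 3.05 (SE 0.69) on the log2 scale, and the helicase-like SPAC212.06c by 2.35 (SE 0.79), whereas per aligned read tlh1 was at -0.56, tlh2 at 0.12 and SPAC212.06c at 0.84 and none of the 3 passed. These 3 of 3 tested members had adjusted p of 0.0153, 0.0102 and 0.0495 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3 fell adjusted over the list alone, but 1 with library totals. The list had camera adjusted p = 0.0291, and adjusted p = 0.289 with an estimated correlation, and the camera p was 0.0663 without 24h replicate 2. These genes have near-identical copies at other chromosome ends, so their counts are uncertain. For tlh1 adjusted p was 0.0677, 0.0834, 0.0869 and 0.0626 without 0h replicate 2, 0h replicate 3, 24h replicate 1 and 24h replicate 3, and 0.0513 with library totals. For SPAC212.06c it lay between 0.0652 and 0.168 without any of 0h replicate 1, 0h replicate 2 or a 24h library, and the count of falls was then 1 or 2. In the mating-type region 4 features were tested, of which the urea transporter gene SPBC23G7.13c rose, from 3 to 225 counts (pooled ratio 14.2, interval 4.80 to 69.5), and SPBC23G7.14 fell by 1.55 (SE 0.38), a change of 1.73 per aligned read. The list did not pass (camera adjusted p = 0.939, with 1 rise and 1 fall also adjusted over the list alone, 1 rise with library totals and 4 rises per aligned read).

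Small RNAs over ste11, the transcription factor that starts sexual differentiation, and mei2, the RNA-binding protein that starts meiosis, rose by 4.21 (SE 0.45) and 4.53 (SE 0.49) on the log2 scale, from 43.3 ± 21.5 to 883 ± 131 and from 49.6 ± 30.3 to 1230 ± 82.0 CPM (SD, n = 3). They were 2 of the 3 tested members of the mating list, also 2 adjusted over the list alone and with library totals, and the other member passed only per aligned read. The list had camera adjusted p = 0.00295, and adjusted p = 0.289 with an estimated correlation. In the nitrogen starvation list 7 of 12 tested members rose and none fell, 7 also adjusted over the list alone, 8 with library totals and 12 per aligned read. The count was 4 without 0h replicate 2 and 4 without 0h replicate 3. The oligopeptide transporter gene isp4 rose by 3.63 (SE 0.54), the oxygenase gene isp7 by 2.78 (SE 0.48), the amino acid transporter gene isp5 by 2.73 (SE 0.59) and the amino acid permease gene per1 by 2.20 (SE 0.47). The list had camera adjusted p = 0.00235, and adjusted p = 0.289 with an estimated correlation. The adjusted p of these 6 genes lay between 0.000494 and 0.00801 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and that of per1 was 0.0528 without 0h replicate 2.

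Genes of the stress response and sugar transporters were also among the rises. In the core stress list 6 of 17 tested members rose and none fell, 9 adjusted over the list alone, 13 with library totals and 17 per aligned read. Among the rises were the phosphatase gene pyp2 (2.68, SE 0.44), the metallothionein gene zym1 (2.97, SE 0.55), the Hsp70 gene ssa1 (2.46, SE 0.48) and sro1 (2.19, SE 0.43), with adjusted p between 0.00262 and 0.00515 in edgeR's quasi-likelihood test with Benjamini-Hochberg. The list had camera adjusted p = 0.000920, and adjusted p = 0.313 with an estimated correlation. Of 6 tested hexose transporter genes 4 rose, 5 adjusted over the list alone and 6 with library totals or per aligned read. The gluconate symporter gene ght3 was at 2.58 (SE 0.71, adjusted p = 0.0216) and ght1 at 2.72 (SE 0.84, adjusted p = 0.0342, edgeR with Benjamini-Hochberg). The list had camera adjusted p = 0.0199, and adjusted p = 0.289 with an estimated correlation. It also did not pass with a minimum count of 30 (0.211) or after thinning (0.175). The hexose count was 0 without 0h replicate 2, 1 without 0h replicate 3, 2 without 0h replicate 1, 24h replicate 1 or 24h replicate 2, and 3 without 24h replicate 3. The ght1 change missed the threshold without each 0h library in turn (0.0741, 0.154 and 0.10), and ght3 without 0h replicate 2, 0h replicate 3 and 24h replicate 3 (0.101, 0.0790 and 0.0684).

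**Figure D3:**
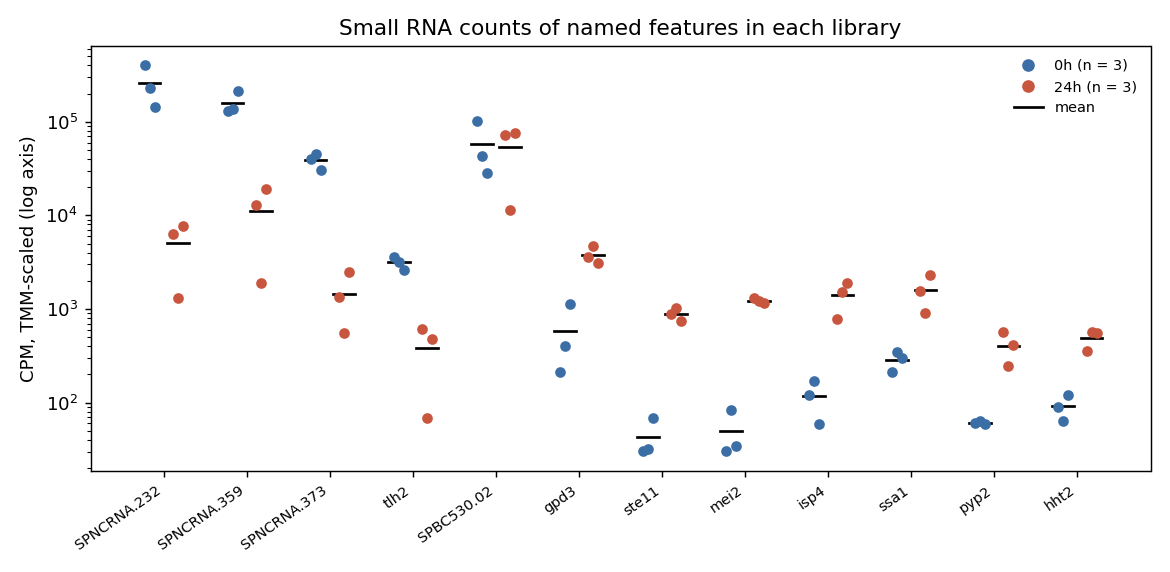
CPM after TMM scaling (log axis) for 12 named features, with 1 point per library, 0h in blue and 24h in red, and a line at the mean of 3 libraries. The pericentromeric SPNCRNA.232 fell from 256962 to 5119 CPM and mei2 rose from 49.6 to 1230 CPM, while SPBC530.02 overlapped; scaled to aligned reads, tlh2 was at a log2 change of 0.12 instead of -3.05.

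Among structural and other noncoding RNAs, 17 of 32 tested tRNA features fell and none rose, 20 adjusted over the list alone, among them SPBTRNATYR.03 (-4.95, SE 0.49) and SPCTRNAGLY.12 (-4.06, SE 0.66), with adjusted p of 0.000494 and 0.00247 in edgeR's quasi-likelihood test with Benjamini-Hochberg. The tRNA median was -1.84 (10 lower with library totals), but 1.40 per aligned read, where 14 were higher and 1 lower. Camera adjusted p was 4.51e-08, and adjusted p = 0.289 with an estimated correlation. Of 43 tested long noncoding RNAs 16 fell and 6 rose, 18 and 8 adjusted over the list alone. The 16 falls included the 5 pericentromeric noncoding RNAs, SPNCRNA.1461 and SPNCRNA.838 (-3.69, SE 0.48, adjusted p = 0.00114, edgeR with Benjamini-Hochberg). The median of the 43 was -0.66, but 0.01 with library totals (11 higher, 14 lower) and 2.94 per aligned read (28 higher, 3 lower). It ran from -2.09 to -0.36 without each library in turn. Camera adjusted p was 0.000854, and adjusted p = 0.289 with an estimated correlation. The rises numbered 3 without 0h replicate 2 and 3 without 0h replicate 3, and the falls 25 without 24h replicate 1. The snRNA and snoRNA list had 2 rises and no fall among 7, also 2 adjusted over the list alone, but 7 rises with library totals or per aligned read (camera adjusted p = 0.0823), with 0 rises without 0h replicate 2 or 0h replicate 3 and 1 without 0h replicate 1.

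The features with the SPMIT prefix, of the mitochondrial genome, had a median of -0.57, but 0.05 with library totals (1 higher, 0 lower) and 2.63 per aligned read (27 higher, 0 lower). Without each library in turn it ran from -1.35 to 0.16, the direction turning without 0h replicate 3. Of 30 tested, SPMIT.08 fell (-1.23, SE 0.36, adjusted p = 0.0297, edgeR with Benjamini-Hochberg) under TMM but was at 2.101 per aligned read, and 0 fell adjusted over the list alone. The list did not pass (camera adjusted p = 0.142). SPMIT.08 missed the threshold without 0h replicate 2, 0h replicate 3, 24h replicate 1 and 24h replicate 2 (0.0710, 0.104, 0.0807 and 0.0983). The list passed without 0h replicate 1 (0.00785) and without 24h replicate 3 (0.00215), where 7 features fell.

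Of 102 tested genes of cytoplasmic ribosomal proteins 6 fell and none rose under TMM scaling, 2 adjusted over the list alone, but 7 rose and 2 fell with library totals and 100 rose and 0 fell per aligned read. The TMM falls included rpl3801 at -3.09 (SE 0.45, adjusted p = 0.00161) and rps2501 at -2.04 (SE 0.45, adjusted p = 0.00846, edgeR with Benjamini-Hochberg), though per aligned read they were at 0.17 and 1.11. The ribosomal list's median of -0.19 was 0.55 with library totals and 3.40 per aligned read, and the list did not pass (camera adjusted p = 0.142). It passed as lower without 0h replicate 3 (0.00432), with a minimum count of 30 (0.0292) and after thinning (0.0103). The falls numbered 3 without 0h replicate 2, 24h replicate 1 or 24h replicate 2. Of 14 glycolysis genes, of which 3 rose with library totals and 14 per aligned read, gpd3, for glyceraldehyde-3-phosphate dehydrogenase, was the 1 that rose under TMM (2.68, SE 0.61, adjusted p = 0.0101, edgeR with Benjamini-Hochberg; 0.0668 without 0h replicate 2), and 1 rose adjusted over the list alone. The glycolysis list had a median of -0.51, but 0.26 with library totals and 3.19 per aligned read (camera adjusted p = 0.579).

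Histone and cell cycle genes went in mixed directions. Of 9 core histone genes the adjacent pair hht2 (2.43, SE 0.39) and hhf2 (1.79, SE 0.35) rose and hht1 fell (-1.61, SE 0.38, but 2.03 per aligned read), with adjusted p of 0.00239, 0.00510 and 0.0113 in edgeR's quasi-likelihood test with Benjamini-Hochberg, and the same numbers of 2 and 1 adjusted over the list alone, but 3 rises and 0 falls with library totals and 9 rises per aligned read. For hht1 adjusted p was 0.0635 without 0h replicate 2. The histone median was -0.10 and the mean 0.22, and the list did not pass (camera adjusted p = 0.734). Of 3 tested G1/S genes nrm1, a repressor of that programme, and cdc22, the large subunit of ribonucleotide reductase, fell by 1.99 (SE 0.48) and 1.18 (SE 0.33) on the log2 scale, adjusted p 0.0138 and 0.0218 (edgeR with Benjamini-Hochberg), 2 also adjusted over the list alone and 1 with library totals, whereas per aligned read they were at 1.143 and 2.52 and 2 of the 3 members rose. For cdc22 adjusted p was 0.0803, 0.0848 and 0.0640 without 0h replicate 2, 24h replicate 1 and 24h replicate 3. The list did not pass (camera adjusted p = 0.171).

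Of 4 tested loci in the list of phosphate-responsive and other small RNA clusters, tgp1, for glycerophosphodiester uptake, rose from 3 to 252 counts (pooled ratio 15.9, interval 5.39 to 77.7). The phosphate transporter gene pho84 rose by 1.61 (SE 0.42), and pho1, the secreted acid phosphatase beside it, fell by 3.42 (SE 0.80) on the log2 scale. Adjusted p was 0.00367, 0.0181 and 0.0115 in edgeR's quasi-likelihood test with Benjamini-Hochberg, with 2 rises and 1 fall also adjusted over the list alone and with library totals, and 3 rises per aligned read (list camera adjusted p = 0.421). For pho84 adjusted p was 0.0618 and 0.0937 without 0h replicate 1 and 0h replicate 2, and for pho1 it was 0.0601 without 24h replicate 1. The pho1 change ran from -3.87 to -1.643 without each library in turn, with the smallest fall without 0h replicate 3. Of 3 tested Mmi1-controlled meiotic genes, mRNAs that are removed in growing cells, none passed by edgeR or adjusted over the list alone; their median was -0.96, but 2.48 per aligned read, where all 3 rose (camera adjusted p = 0.320). Without 0h replicate 2, and without 24h replicate 3, 1 of them passed as lower.

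**Figure D4:**
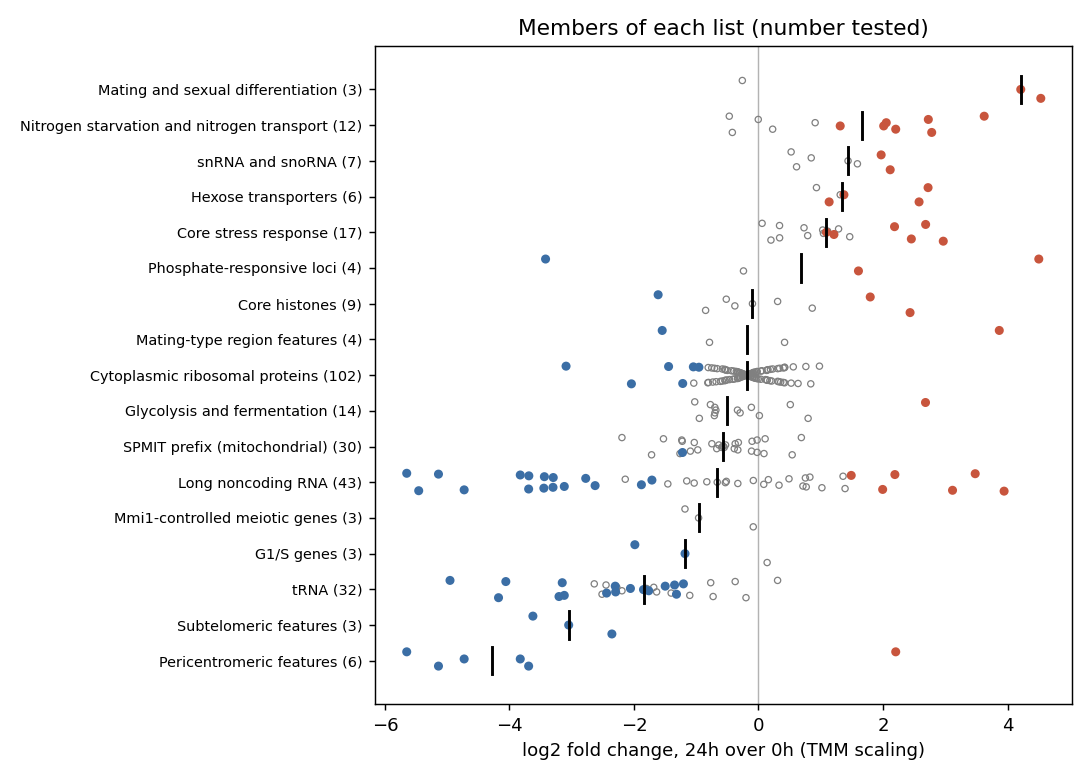
Log2 fold change of each tested member of 17 lists, 24h over 0h under TMM scaling; filled points passed edgeR's test (red higher, blue lower), open points did not, and the black mark is the list median. The pericentromeric median was -4.28 and the mating median 4.21 (-4.96 to -3.82 and 2.04 to 4.25 without each library in turn, the mating list not being testable without 24h replicate 2); per aligned read the medians of the lists left of 0 became positive, except the pericentromeric list at -1.18.

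Genes of the RNA interference and heterochromatin machinery had few small RNAs. The 24 genes summed to 1249, 1270 and 1152 CPM of assigned reads at 0h and 1563, 1704 and 1270 at 24h, and 2 of them had enough counts for a test. Small RNA over ago1 itself was at a log2 change of -0.11 (SE 0.34, adjusted p = 0.841), positive with totals (0.64) and aligned reads (3.50), and rdp1, for the RNA-dependent RNA polymerase, at -0.75 (SE 0.42, adjusted p = 0.204), positive with aligned reads (2.62), in edgeR's quasi-likelihood test with Benjamini-Hochberg. The Dicer gene dcr1 had 8 counts at 0h and 85 at 24h, and the histone H3K9 methyltransferase gene clr4 10 and 45, too few for the filter. The 20 wtf driver features held 265 counts over the 6 libraries. The 13 Tf2 retrotransposon features held 0 counts, which allows up to 62.4 CPM of assigned reads in the shallowest library and 3.95 in the deepest, for sequence that can be placed uniquely.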

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

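The tests per aligned read, against reads in no feature, of the SPMIT features, of the 38 list members and of depth were chosen only after the result was seen. Reads that overlapped more than 1 feature were kept out of every comparison, and their share of uniquely placed reads was above that of the 0h libraries in each 24h library. It was 1.04%, 1.84% and 1.19% at 24h against 0.0801%, 0.121% and 0.459% at 0h (exact permutation p = 0.10, the smallest possible). Reads in no feature fell from 88.0% to 47.0% of uniquely placed reads, which raises the share of all other reads. Set against assigned reads, the groups overlapped. In 0h replicate 3 there were 3966 such reads to 145861 assigned, and in 24h replicate 1 there were 1061 to 54393.

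The 5 pericentromeric noncoding RNAs were lower at 24h. Dilution by other assigned reads alone would let the groups overlap as CPM of aligned reads, but every 24h library stayed below every 0h library, with means 2.73-fold apart. With a linear trend in log2 assigned depth removed over the 6 libraries, the log2 difference of their share was -4.17 (95% interval -7.50 to -0.84), which argues against depth. A loss shared by all uniquely placed small RNA in no feature cannot be told apart. Set against reads in no feature, the 5 were at 5.37%, 3.88% and 7.12% at 0h. At 24h they were at 4.204%, 0.896% and 3.27%, means 1.96-fold apart with an overlap. Reads in no feature may include those from the opposite strand of the 5, so this ratio cannot decide. Reads in no feature were themselves 4.25% ± 1.18 of aligned reads at 0h and 3.19% ± 0.852 at 24h (SD, n = 3, exact permutation p = 0.20). That fall of 1.33-fold was smaller than the 2.73-fold fall of the 5, and its groups overlapped. A smaller supply of pericentromeric small RNA in quiescent cells stays open as a biological explanation, and over 90% of aligned reads, which may hold most repeat-derived small RNA, were not counted.

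Assigned reads were a larger share of aligned reads at 24h. The shallowest and the deepest library were both 24h, and with a linear trend in log2 aligned depth removed the log2 difference was 2.49 (95% interval 1.141 to 3.84), which argues against depth as the whole cause. RNA fragments carried over without Ago1 may contribute, and SPMIT features, whose transcripts lie in mitochondria, cannot decide this. Per aligned read their median log2 change was 2.63, with 27 of 30 called higher. On that scale 1611 of all 1716 tested features were called higher, with a median of 3.55, and protein-coding features had a median of 3.61. Almost any set of features rises on it. Loading of Argonaute with small RNA from genes in starved cells stays open and was not tested, as no library of RNA without Ago1 was analysed here.

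Of 38 tested members of the mating, nitrogen starvation, stress and hexose transporter lists, 19 rose and 0 fell, and the median log2 change of all 38 was 1.25 (95% bootstrap interval 0.987 to 2.03). These 4 lists were the ones that camera had called higher, so a median above 0 followed from that choice. The bootstrap drew genes, not libraries, so its intervals leave out the spread between libraries. With an estimated correlation the 4 lists had camera adjusted p of 0.289 to 0.313. Without 24h replicate 3, the deepest library, the median of the 37 tested was 1.13 (0.73 to 1.92). The rise therefore did not rest on that library alone. Among 1000 draws of protein-coding features matched for length the highest median was 0.807. Camera had picked these lists as higher than other features in these same libraries. A median above such draws followed from that choice too, so the draws cannot decide on gene length. With a linear trend in log2 assigned depth removed, the log2 difference of the members' median CPM was 1.63 (95% interval 1.145 to 2.12). The members were picked for a difference between these same groups, so that value does not decide on depth either. Degraded fragments of mRNAs that starvation induces, and small RNAs made from those genes, both stay open, since mRNA levels were not analysed here.

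Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many as 444 changed features, and the highest other split gave 0. With 10 splits no share below 0.05 can be reached.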

How the results depend on the processing

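Scaling by aligned reads and thinning were chosen after the data had been seen; the other settings were planned. The numbers of higher and lower features were 568 and 95 with library totals, 479 and 337 with no filter (6207 features tested), 100 and 76 with a minimum count of 30 (543 tested), 1611 and 4 with aligned reads and 89 and 67 after thinning (567 tested). Without each library in turn the higher count ran from 110 to 204 and the lower from 147 to 235. With DESeq2 they were 252 and 241 (3 features had no adjusted p) and with limma-voom 216 and 251. No feature called higher became lower in any setting, but 129 of the 220 lower features were called higher with aligned reads. The cause of these differences was not tested. The fewest calls among the left-out settings came without 0h replicate 2.

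The deviations of libraries with the same replicate number correlated at 0.0121, 0.108 and 0.133, not all over 0.1, and they were treated as unpaired. With the replicate block 279 features were higher and 271 lower, of which 221 and 214 were shared. The snRNA and snoRNA list then had adjusted p = 0.0335 and the SPMIT list 0.0281; among the named features SPAC212.06c no longer passed (0.0910).

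With an estimated correlation no list passed: adjusted p was 0.289 for the mating, nitrogen, hexose, pericentromeric, subtelomeric, tRNA and long noncoding lists and 0.313 for stress. The directional test of fry gave 0.0310 for Mmi1 targets and 0.00765 for G1/S genes. Its mixed test gave 0.0322 for phosphate loci, 0.000947 for ribosomal proteins, 7.75e-05 for glycolysis, 0.00628 for histones, 0.0376 for G1/S, 0.0218 for the mating-type region and 0.102 for subtelomeric features. With no filter, ribosomal proteins (0.765), glycolysis (0.841) and the mating-type region (0.144) changed direction without passing, and G1/S genes (0.00667), snRNA and snoRNA (0.00111) and subtelomeric features (0.137) crossed the threshold. With a minimum count of 30, ribosomal proteins had 0.0292, hexose transporters 0.211 and long noncoding RNAs 0.127; after thinning the values were 0.0103, 0.175 and 0.0759. With library totals the SPMIT list had 0.0263. Leaving out each library gave ranges of 0.00432 to 0.477 for ribosomal proteins, 0.715 to 0.951 for the mating-type region with changes of direction, 0.00932 to 0.0663 for subtelomeric features, 0.0195 to 0.311 for snRNA and snoRNA, and 0.00215 to 0.994 for SPMIT, with a change of direction without 0h replicate 3. The list medians then ran from -2.09 to -0.36 for long noncoding RNAs (-0.66 with all libraries), from -1.35 to 0.16 for SPMIT (-0.57), from 2.04 to 4.25 for mating (4.21) and from 0.57 to 1.59 for snRNA and snoRNA (1.44). The tested members differed between these settings. The medians ran from 0.98 to 1.45 for nitrogen starvation (1.66), from -4.96 to -3.82 for pericentromeric features (-4.28), from -3.43 to -2.52 for subtelomeric features (-3.05), from -2.36 to -1.61 for tRNA (-1.84) and from 0.78 to 1.20 for stress (1.09). They ran from 0.29 to 1.01 for phosphate loci (0.68), from -1.42 to -1.05 for G1/S genes (-1.18), from -0.41 to -0.08 for ribosomal proteins (-0.19), from -0.41 to 0.05 for the mating-type region (-0.18) and from -0.28 to 0.00388 for histones (-0.10). The mating list had too few tested members under the strict filter, thinning and without 24h replicate 2, and the subtelomeric list under the strict filter and thinning.

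As log2 ratios of shares of aligned reads, 24h over 0h, protein-coding features were at 3.68, SPMIT 2.93, tRNA 2.15, snRNA and snoRNA 4.98 (1.34 to 2.28 as shares of assigned reads without each library), long noncoding RNA 0.20, other features 2.46, pericentromeric features -1.33, the 5 pericentromeric noncoding RNAs -1.45, the mating-type region 3.13 and subtelomeric features 0.47. As fold changes of these shares, leaving out each library gave 12.9 to 41.3 for snRNA and snoRNA, 5.72 to 10.7 for the mating-type region, 3.53 to 7.28 for other features and 5.64 to 14.9 for SPMIT, and falls of 2.06 to 3.23 for pericentromeric features.

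Of 67 named features 60 passed. Of these, 13 no longer passed without 0h replicate 2, 7 with library totals, 4 with no filter and 2 with limma-voom, and 12 more kept their direction but no longer passed with aligned reads. The mfs2 rise, which had not passed, passed with library totals (3.01), no filter (2.77), DESeq2 (2.37), aligned reads (5.51) and without 24h replicate 2 (2.88), and SPCTRNAARG.10 passed as lower without 24h replicate 1 (-2.06). With aligned reads the direction changed for SPBC530.02 (3.13), srp7 (3.24), SPMIT.01 (3.14), tlh2 (0.12), ago1 (3.50), rdp1 (2.62), rpl3801 (0.17), rps2501 (1.11), hht1 (2.03), nrm1 (1.143), cdc22 (2.52), SPBC23G7.14 (1.73), SPAC212.06c (0.84), SPMIT.08 (2.101), mrpl24 (0.98) and SPCTRNAARG.10 (3.20). With library totals it changed for SPBC530.02 (0.56), srp7 (0.40), SPMIT.01 (0.53), ago1 (0.64) and SPCTRNAARG.10 (0.38), with no filter for SPBC530.02 (0.32), srp7 (0.0257), SPMIT.01 (0.21) and ago1 (0.25), and with limma-voom for ago1 (0.00781). Without each library in turn the ranges were -0.53 to 0.57 for SPBC530.02, -0.87 to 0.67 for SPMIT.01, -0.30 to 0.14 for ago1 and -2.06 to 0.11 for SPCTRNAARG.10. Over 1.5-fold moves were seen for 33 of 67 features, among them those 3 other than ago1. The ranges of the others were 4.05 to 10.23 for SPAC869.04, 4.83 to 9.13 for psu2, -6.26 to -3.23 for SPCTRNALEU.11, -7.46 to -4.93 for SPNCRNA.1461, 6.52 to 8.72 for prl65, -3.87 to -1.643 for pho1, 3.84 to 6.26 for SPCPB16A4.06c, 3.80 to 5.76 for eno102, 6.30 to 8.08 for hsp3105, -4.46 to -2.29 for tlh1, -4.37 to -2.88 for mrp20, 3.53 to 5.29 for SPAC869.03c, -4.71 to -3.15 for SPNCRNA.234, 2.91 to 4.68 for SPBC23G7.13c, 4.02 to 5.79 for SPAC2H10.01. They were -2.95 to -1.67 for rps2501, 4.01 to 5.38 for tgp1, -2.85 to -1.53 for nrm1, -4.53 to -3.42 for SPNCRNA.838, 2.30 to 3.52 for gpd3, 4.48 to 5.91 for nrg1, 1.91 to 3.11 for ght1, -3.80 to -2.80 for rpl3801, -5.43 to -4.33 for SPNCRNA.373, -4.52 to -3.32 for SPNCRNA.359, 2.06 to 3.41 for isp5, 4.14 to 5.20 for mei2, 2.30 to 3.39 for zym1, -5.58 to -4.48 for SPNCRNA.231 and 1.76 to 2.88 for mfs2. The ranges of prl65 and hsp3105, which had no count at 0h, are fitted values and do not measure a size. The same holds for the upper ends of SPAC869.04 and psu2, whose 0h counts all lay in 1 library.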

Other observations

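The word test and the tRNA values were chosen only after the result was seen. The word groups overlap the lists described above. Among protein-coding features, genes whose reference description holds the word transporter rose more often than others, 31 of 88 (35.2%, with 9 lower) against 13.5% of all 1603 tested, as did those with the word transcription, 16 of 48 (33.3%). Fisher's exact test, Benjamini-Hochberg adjusted over 130 tests of 65 words, gave adjusted p of 4.78e-06 and 0.0124. Transporter genes that rose included SPBC1271.10c (4.08, SE 0.58), the urea transporter gene SPAC869.03c (4.25, SE 0.71), the phosphate transporter gene pho841 (3.37, SE 0.55) and mfs1 (3.01, SE 0.50), and transcription factor genes sfp1 (3.04, SE 0.41), gaf1, a GATA factor of nutrient sensing (2.51, SE 0.35), rsv2 (2.33, SE 0.41) and the oxidative stress factor pap1 (2.22, SE 0.38), all log2 changes with adjusted p between 0.00125 and 0.00351 in edgeR's quasi-likelihood test with Benjamini-Hochberg.

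None of 134 features with the word ribosomal rose under TMM scaling (Fisher's exact test, adjusted p = 3.36e-07), and 11 fell (adjusted p = 0.798), among them the mitochondrial ribosome genes mrp20 (-3.22, SE 0.51) and mrpl24 (-2.40, SE 0.46, but 0.98 per aligned read), with adjusted p of 0.00220 and 0.00465 in edgeR's quasi-likelihood test with Benjamini-Hochberg. These words were counted under TMM scaling alone.

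Small RNAs from overlapping sense and antisense transcripts were considered as a possible explanation for the protein-coding rises. An annotated feature on the opposite strand overlapped 85 of 216 risers (39.4%) and 661 of 1387 other tested protein-coding features (47.7%). The odds ratio was 0.713 (two-sided Fisher's exact p = 0.0232), the opposite of what that explanation predicts for rises under TMM scaling. Per aligned read 1534 of 1603 tested protein-coding features were called higher. The comparison therefore cannot speak to that wider rise, and annotation does not show that an opposite-strand transcript was present. A second hypothesis was that neighbouring genes rise together. Of 560 adjacent pairs of tested protein-coding features 16 had both members higher, where 10000 permutations of the calls gave a mean of 10.1, a highest value of 25 and a one-sided p of 0.044. The pairs included hhf2 and hht2, ght8 and ght1, tgp1 and SPBC1271.10c, atf1 and isp4, and SPAC869.04 and SPAC869.03c. Shared regulation of neighbours, or small RNA crossing gene boundaries, may underlie this, and the test does not part them.

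By reference positions the pericentromeric windows held 42 tRNA features, of which 3 were tested. SPBTRNATYR.03 (-4.95, SE 0.49) and SPCTRNALEU.11 (-4.18, SE 1.00) had the largest falls of the 32 tested tRNA features, and SPCTRNAARG.10 was at -0.37 (SE 0.82), but passed as lower without 24h replicate 1 (-2.06, edgeR adjusted p = 0.0244). Their adjusted p was 0.000494, 0.0131 and 0.767 in edgeR's quasi-likelihood test with Benjamini-Hochberg. For SPCTRNALEU.11 it was 0.0677, 0.166, 0.0999 and 0.0786 without 0h replicate 1, 0h replicate 2, 24h replicate 1 and 24h replicate 3, and per aligned read the changes were -1.638, -0.10 and 3.20.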
